A study of Mus musculus with 6 samples.

How the data were processed

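Total RNA of 6 stable clones of the mouse fibroblast line NIH3T3, 3 with human FEAT and 3 with the vector without ccdB, was extracted on RNeasy columns, amplified with the Illumina TotalPrep kit, labelled with Cy3 and hybridised to 1 Illumina mouse bead array per clone, per the labels' protocols. BeadStudio was used, per the submitters' processing notes, and its version was not given in the sources used here. Groups and clone numbers came from the sample titles. The clones were separate stable lines, and the numbers only name them, since the groups are numbered 1, 2, 3 and 3, 15, 20. Growth conditions, passage and slide were not given in the sources used here.

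The deposited values were linear probe intensities of each array, 45281 per array, with no detection p or bead number in the tables used here. Their lowest values lay between 50.1 and 53.1, so background had not been subtracted, and their medians, 81.9 to 88.2, differed between arrays. The deposited value table of the series held the same intensity values multiplied by 1 factor per array (0.925 to 1.10), which gave every array a mean of 680. It was on a linear scale, not centred by gene, with medians of 81.6 to 92.6, and was used as an alternative.

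The arrays were processed with R 4.3.3 and limma 3.58.1. Before the data were examined, the test, the filter, the threshold, the rule for named genes, the gene lists and the alternatives were fixed. The plan was neqc, which takes the background from detection p. Without detection p, the normexp model was fitted to the signals themselves with the same offset of 16, followed by quantile normalization and log2. For the same reason the planned detection filter was replaced by its stated fallback, the top 60% of probes by mean over the 6 arrays, which left 27169 probes. A filter on detection at p under 0.01 on all 6 arrays and a slide block were planned and not run. The normexp step draws dim probes apart on the log2 scale, so folds of dim genes depend on it.

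Each probe was tested with lmFit and eBayes on the 3 FEAT against the 3 control clones, with a two-sided moderated test and Benjamini-Hochberg adjustment over all probes tested, at an adjusted p under 0.05. An exact permutation test of 3 against 3 cannot give a two-sided p below 0.1, so none was used for single genes. Log2 differences are FEAT minus control. Intensities in the text are means and SDs of the deposited values, and folds come from the normalized log2 values, so their ratios can differ. For counts by gene and for lists, the probe with the highest mean stood for its gene, and where probes of a named gene differed the text gives the other tested probes.

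A background limit was set for each array after the data were seen, at the mode of its log2 intensities plus 3 SDs of the values below the mode. A gene below this limit on every array of a group has only a bound there. The bound is the mean of the bright group against the mean, over the dim group's arrays, of the higher of the limit and the probe's own value, all on normalized log2 values. Deposited intensities still hold the background, so their ratio is smaller than a ratio of background-corrected values, and such bounds depend on the correction.

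Probes were named through the GEO platform annotation and a RefSeq gene table of assembly GRCm38.p6. Of the 45281 probes, 34885 had 1 gene, 18 had several and were not named, and 10378 were unnamed here. Gene IDs of 34807 probes were in the current gene table, and 0 symbols needed an update. The array covered 19057 named genes, and 13315 were tested. Coordinates were left out, since the build of the array design was not given in the sources used here.

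The text names the mouse counterpart of FEAT, the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold with no overlap between groups, and up to 4 members of each list with the smallest unadjusted p. Acta2 and the lower MAPK feedback genes Dusp4, Etv4 and Spred2 are outside this rule and were named after their values were seen. For Dusp4, Etv4 and Spred2 only the brightest probe is given, without its place against the background limit.

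The 31 gene lists covered hedgehog, receptor tyrosine kinases and their ligands, MAPK feedback, apoptosis, p53, cell cycle, matrix, contractile genes, TGF-beta, Wnt, Notch, immune responses, stress responses, metabolism, translation, adhesion and markers of 7 other cell types. Of 893 list entries, 892 matched a gene. Lists were tested two-sided with limma's camera at a preset correlation of 0.01, adjusted over the 31 lists. Camera with an estimated correlation called 0 lists, and fry called 1.

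The steps were tested on simulated data for FEAT against control, 3 against 3, on 27169 probes with 50 probes changed at each fold. At 1.5-fold 36% were recovered, and at 2-fold, 3-fold and 4-fold 100%. Of 183 calls, 15 (8.20%) were false. In 8 of 10 runs with no changed probe at least 1 probe was called, with 6 calls at most. The shifted list was found and 0 unshifted lists were called. The simulated noise was independent between probes, so these runs cannot show how often camera calls lists whose genes vary together, as on real arrays. It was normal with the moderated SD of each probe, which draws in large SDs, so recovery on the real arrays may be lower. There Actg2, 6.45-fold higher in FEAT clones, did not pass (limma, adjusted p = 0.0995).

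Alternatives were no normexp (log2 of the signal with a floor of 16), an offset of 50, median scaling, cyclic loess, the deposited value table, no filter, an intensity trend in eBayes with and without robust estimation, array weights, stricter and looser thresholds, the mean of all probes of a gene, and leaving out each clone in turn. The 10 splits of the 6 clones into 3 and 3 were refitted. statmod 1.5.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were also used.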

Results

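Gene expression was measured in 6 stable clones of NIH3T3, an immortalized line of mouse embryonic fibroblasts from NIH Swiss mice. The 3 FEAT clones (FEAT 3, FEAT 15 and FEAT 20) carried the open reading frame of human FEAT, also known as METTL13 or EEF1AKNMT, a methyltransferase that modifies the translation elongation factor eEF1A. The insert was driven by the promoter of the elongation factor 1 alpha gene, the cells were selected for 7 days with 10 µg/ml blasticidin S, and the clones were chosen for high FEAT protein. The 3 control clones (control 1, control 2 and control 3) carried the same vector with its ccdB gene removed and no FEAT. Whether they went through the same selection was not given in the sources used here. Total RNA of each clone was hybridised to 1 one-colour Illumina bead array with 45281 probes. The mean probe intensity was 717, 652 and 652 on the arrays of control 1, control 2 and control 3, and 616, 710 and 735 on those of FEAT 3, FEAT 15 and FEAT 20. Between 39.4% and 43.0% of probes lay above the background limit of their array. The number of arrays limits the precision of every value below.

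The comparison asked which transcripts differ between fibroblasts that overexpress FEAT and fibroblasts with the empty vector. The transfected gene was looked at first. All 5 probes of the mouse gene Eef1aknmt, the counterpart of human FEAT, were tested, and none passed the threshold. The brightest read an intensity of 677 ± 68.8 in control clones and 712 ± 57.7 in FEAT clones (SD, n = 3 clones each), a log2 difference of 0.03 (limma, adjusted p = 0.979). Another probe was dimmer in all 3 FEAT clones, at 94.2 ± 4.15 against 119 ± 1.92, with 1 of 3 FEAT arrays above the background limit, a log2 difference of -0.59 that did not pass (adjusted p = 0.146). The remaining log2 differences were -0.25, -0.17 and -0.11. The insert was human and the probe sequences were not used here, so these mouse probes need not read the transgene and give no check of its level.

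Ccn5, a matricellular protein of the CCN family, rose 4.06-fold in the FEAT clones, from an intensity of 399 ± 153 in the control clones to 1484 ± 474 in the FEAT clones (SD, n = 3 each; log2 difference 2.02, SE 0.31, adjusted p = 0.0321). Ptx3, a secreted pentraxin of innate immunity, rose 3.56-fold (log2 1.83, SE 0.16, adjusted p = 0.00242), with a log2 difference of 1.81 on its other probe, which also passed. Ccn2, known as connective tissue growth factor, rose 2.29-fold from 14030 ± 2089 to 32470 ± 3852 (adjusted p = 0.0192), and its other probe passed too, at 1.27. Fgf7, the keratinocyte growth factor, rose 2.56-fold from 2575 ± 662 to 6572 ± 1337 (adjusted p = 0.0192). Genes that fell included Itgbl1, an integrin beta-like protein, by 1.43 on the log2 scale (SE 0.15, adjusted p = 0.00970), and Chac1, a glutathione-degrading enzyme induced by ATF4, whose intensity was 9158 ± 1703 in control clones and 3626 ± 833 in FEAT clones (log2 -1.40, adjusted p = 0.0376).

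Other genes that rose included Scara5, a scavenger receptor that binds ferritin, with a 3.58-fold change (adjusted p = 0.0420), although its other probe differed by 0.19. Thbs1, which encodes the matrix glycoprotein thrombospondin, rose 2.47-fold (adjusted p = 0.0237), with 2 of 3 control arrays above the background limit. Dysf, the membrane repair protein dysferlin, rose 2.37-fold on its brightest probe (adjusted p = 0.0243), while its other probes differed by 0.24, 0.70 and 0.63. The transcription factors Junb and Egr1, both early response genes, rose 2.22-fold and 2.01-fold (adjusted p = 0.0211 and 0.0237). Smad6, an inhibitor of BMP signalling, rose 2.12-fold (adjusted p = 0.0192), and Gadd45b, a stress-inducible gene, 1.77-fold (adjusted p = 0.0420). Amhr2, the receptor of anti-Müllerian hormone, rose 2.11-fold (adjusted p = 0.0235), with 0.09 on its other probe. Tmem181a and the P4-type ATPase gene Atp9a were not above background on any control array, which leaves only a bound: they were at least 2.04-fold and at least 1.47-fold higher in FEAT clones (adjusted p = 0.0481 and 0.0375). The other Atp9a probe, also not above background on any control array, passed too (adjusted p = 0.0237), while the other Tmem181a probe did not pass and was above background on 1 FEAT array alone. Tmem181a has close relatives in the mouse genome, and which copies its probe reads is uncertain.

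Among the other genes that fell, Uap1l1, a relative of a nucleotide sugar pyrophosphorylase, read 7148 ± 1372 in control clones and 3334 ± 781 in FEAT clones (SD, n = 3 each; log2 -1.15, adjusted p = 0.0192). Efna1, a membrane-bound ligand of Eph receptors, fell by 0.96 on the log2 scale and Clba1 by 1.06 (adjusted p = 0.0192 for both). The sialyltransferase gene St3gal6 fell by 1.22 (adjusted p = 0.0237), and its other probe was not above background on any FEAT array. Steap3, a ferrireductase, fell by 0.95 on its brightest probe (adjusted p = 0.0192), whereas its other probes differed by 0.11 and -0.25 or were not above background on any array. Capn6, a calpain without the usual catalytic cysteine, fell by 1.23 (adjusted p = 0.0310), with 1 of 3 FEAT arrays above the background limit. Bglap2, an osteocalcin gene with close copies, fell by 1.06 (adjusted p = 0.0420). Rgcc, a regulator of the cell cycle, fell by 0.84 (adjusted p = 0.0366), and the predicted gene Gm17597 by 0.99 (adjusted p = 0.0341). Mroh1 was not above background on any FEAT array and was at least 1.29-fold lower there (adjusted p = 0.0493).

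**Figure D1:**
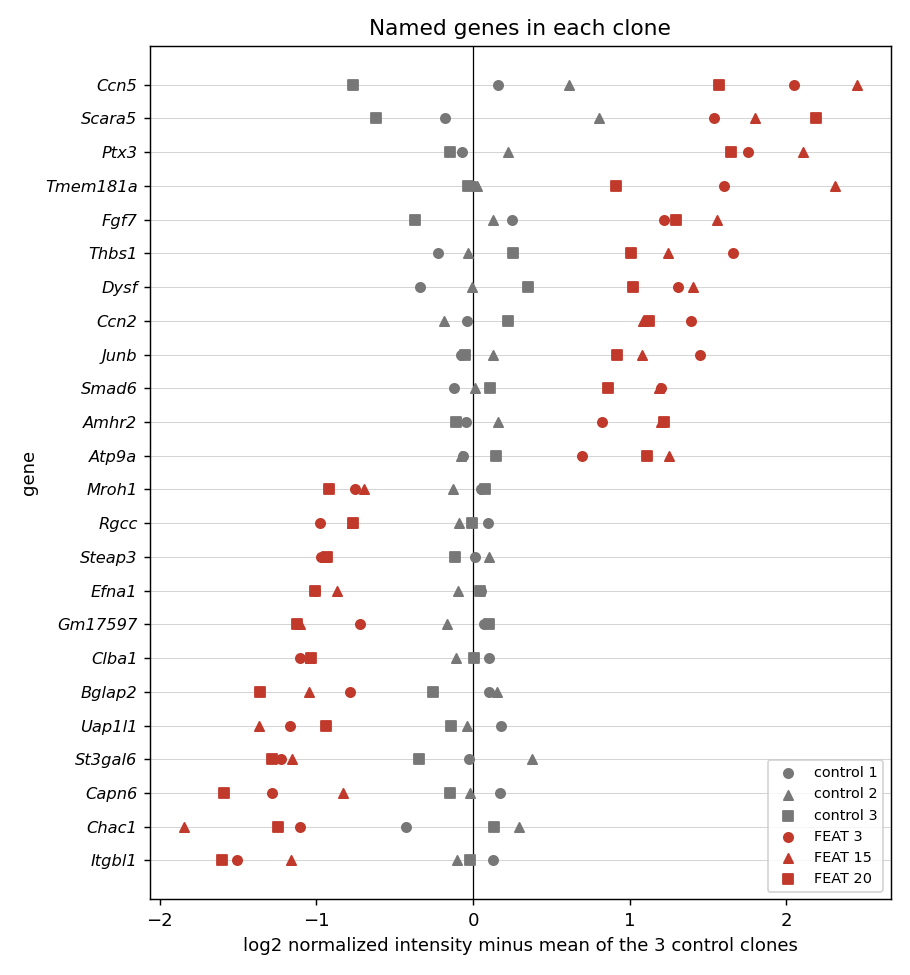
Normalized log2 intensity of each named gene in each clone, as the difference from the mean of the 3 control clones (horizontal axis), with 1 symbol per clone, grey for control and red for FEAT. The 12 genes with the largest rise and the 12 with the largest fall among the genes past the threshold are drawn, and in each of them all 3 FEAT clones lie on 1 side of all 3 control clones.

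Over all 27169 probes tested, 50 passed an adjusted p of 0.05, 32 of them higher and 18 lower in the FEAT clones. They belonged to 36 named genes, 22 higher and 14 lower, and to 10 probes without a gene name here. In all 50 the 3 clones of one group lay above the 3 of the other. Sizes ran from 0.76 on the log2 scale to a rise of 2.02 and a fall of -1.62. An unadjusted p under 0.05 was reached by 2467 probes, 9.08% of those tested. With 1 probe per gene, 52 of 13315 genes differed at least 2-fold with no overlap between the groups, 30 higher and 22 lower. That number was 105 without control 2, 89 without FEAT 15, and 32 both without normexp and with the deposited value table. With a clone left out, the groups separate more easily by chance, so 105 and 89 cannot be set directly against 52. Without regard to size, 15.2% of genes had no overlap, where chance gives 10%. The count changed with the clones included: limma called 0 probes without control 1 (1934 at an unadjusted p under 0.05), 158 without control 2, 10 without control 3 and 18 without FEAT 3. Of the 26 genes named here and called on their brightest probe, 14 kept their call in every scaling, filter and variance setting. None kept it in all 6 omissions of a clone. None changed sign, which an omission could hardly bring about where the groups do not overlap. Ptx3 and Itgbl1 kept it in 9 of 9 settings and 5 of 6 omissions. Ccn5 kept it in 6 of 9 settings and 2 of 6 omissions, and Scara5 and Chac1 in 6 of 9 and 1 of 6. Tmem181a and Mroh1 kept it in 4 and 3 of 9 settings, and Bglap2 in 0 of 6 omissions.

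Genes of cholesterol synthesis, the pathway from acetyl-CoA to cholesterol, were lower as a group in the FEAT clones. The mean log2 difference over 18 measured genes was -0.50 and 17 of the 18 were negative (camera, adjusted p = 5.92e-12, and adjusted p = 0.462 with an estimated correlation). No gene was called on its brightest probe over all genes tested, and 9 were lower when adjusted over the list alone. Nsdhl, a sterol dehydrogenase, had a log2 difference of -0.91 on its brightest probe (adjusted p = 0.0697), and it passed on other probes, at -1.08 and -0.76 (adjusted p = 0.0192 and 0.0493). Dhcr7, which catalyses the last step of the pathway, differed by -0.88, the mevalonate pathway kinase Pmvk by -0.94 and the farnesyl diphosphate synthase Fdps by -0.71, although the other probe of Fdps gave 0.19. Against the control mean, the list's mean was -0.57, -0.43 and -0.50 in FEAT 3, FEAT 15 and FEAT 20, and 0.28, -0.24 and -0.04 in control 1, control 2 and control 3.

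Genes of the extracellular matrix were higher as a group, with a mean log2 difference of 0.30 over 39 measured genes (camera, adjusted p = 9.06e-07, and adjusted p = 0.462 with an estimated correlation). Of these, 28 were positive. Ccn2 and Thbs1 rose over all genes tested, and 10 genes were higher when adjusted over the list alone, among them the collagen gene Col5a1 at 0.74 and the microfibril gene Mfap5 at 0.98. The list's mean was 0.46 in FEAT 3 and 0.35 in FEAT 15, but 0.083 in FEAT 20.

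Contractile and myofibroblast genes were also higher as a group, with a mean of 0.46 and a median of 0.28 over 20 measured genes (camera, adjusted p = 5.05e-05, and adjusted p = 0.462 with an estimated correlation). None was called over all genes tested and 4 were higher when adjusted over the list alone. The smooth muscle genes Actg2, Tagln and Myl9 had log2 differences of 2.69, 1.82 and 1.36 (adjusted p = 0.0995, 0.0887 and 0.161 over all genes), and the tropomyosin gene Tpm1 of 0.46. Acta2, the usual myofibroblast marker, differed by -0.09 on its brightest probe, the one the list used, and by 1.05, 0.96 and 0.99 on its other probes, none of which passed (adjusted p = 0.0701, 0.0836 and 0.0887). The list's mean was 0.67 in FEAT 3 and 0.53 in FEAT 15, but 0.18 in FEAT 20.

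TGF-beta and SMAD target genes had a mean log2 difference of 0.34 over 18 measured genes (camera, adjusted p = 1.16e-04, and adjusted p = 0.462 with an estimated correlation). Smad6 rose over all genes tested and 5 genes were higher when adjusted over the list alone. Among them were Ltbp3, a latent TGF-beta binding protein, at 0.74, the activin subunit gene Inhba at 0.69 and Id2, an inhibitor of differentiation, at 0.73. The other probes of Ltbp3 gave 0.93, which passed over all probes (adjusted p = 0.0481), and 0.46, and those of Id2 gave 0.50 and 0.35. The list's mean was 0.099 in FEAT 20, below the 0.14 of control 3.

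The Wnt list had a mean of 0.21 and a median of 0.089 over 24 measured genes (camera, adjusted p = 0.0259, and adjusted p = 0.462 with an estimated correlation). Ccn5 rose over all genes tested, and it was the 1 gene higher when adjusted over the list alone. Wnt5a differed by 0.53, its receptor family member Fzd1 by 0.52 and Ccn4 by 0.74. Of the other probes of Wnt5a, one gave 0.32 and one was not above background on any array, and that of Ccn4 gave 0.45. The Wnt call was lost with the deposited value table and without control 2 or FEAT 3 (adjusted p = 0.0534, 0.146 and 0.0583). Inflammatory cytokines and chemokines had a mean of 0.17 over 21 measured genes (camera, adjusted p = 0.0495, and adjusted p = 0.534 with an estimated correlation). None was called over all genes tested, and the chemokine gene Cxcl1, at 0.65, was the 1 gene higher when adjusted over the list alone. This call was kept in 2 of 7 scaling, filter and probe settings and in 3 of 6 omissions of a clone, with adjusted p up to 0.460 in the omissions. Over the 10 splits of the 6 clones into 3 and 3, the real one included, camera called the cholesterol list in 6, the matrix, contractile and TGF-beta lists in 4 each, the inflammatory list in 3 and the Wnt list in 2.

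**Figure D2:**
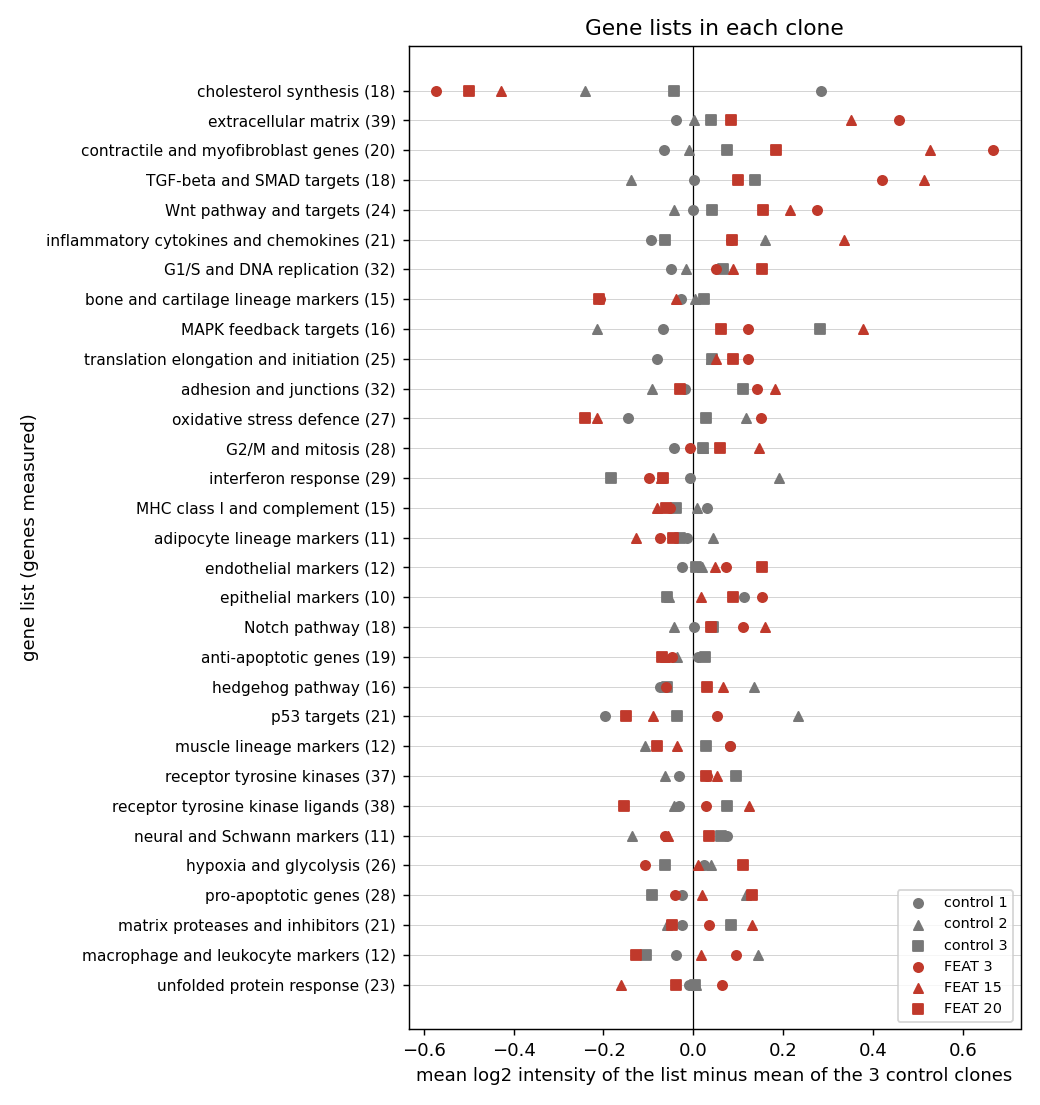
Mean normalized log2 intensity of each of the 31 gene lists in each clone, as the difference from the mean of the 3 control clones (horizontal axis), with the number of measured genes in brackets and 1 symbol per clone, grey for control and red for FEAT. In the cholesterol synthesis list the FEAT clones lie at -0.57, -0.43 and -0.50, below all 3 control clones, while in the TGF-beta and SMAD list FEAT 20, at 0.099, lies within the range of the controls.

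The other 25 of the 31 lists did not pass with camera. Several of them held genes that went opposite ways. Ligands of receptor tyrosine kinases had a mean of -0.00071 over 38 genes (adjusted p = 0.821), with Fgf7 higher and Efna1 lower over all genes tested, and 4 higher and 3 lower when adjusted over the list alone. Among the latter were Hbegf, an EGF receptor ligand, at 1.07 (adjusted p = 0.0534 over all genes) but 0.08 on its other probe, which was not above background on any control array, and Kitl, the ligand of Kit, at -0.80 (adjusted p = 0.0891). MAPK feedback targets had a mean of 0.19 (adjusted p = 0.107, but 0.33 and 0.0163 without control 3 and 0.25 and 0.0272 without FEAT 20), with Egr1 called, and 4 higher and 3 lower when adjusted over the list alone. The early growth response genes Egr3 and Egr2 differed by 1.34 and 1.37 there, with -0.11 on the other probe of Egr3, and the phosphatase gene Dusp5 by 0.97. The 3 lower genes were Dusp4, at -1.06, Etv4, at -0.78, and Spred2, at -0.42. Matrix proteases and their inhibitors had a mean of 0.040 (adjusted p = 0.909), with 0 called over all genes and 3 higher and 3 lower when adjusted over the list alone. Among the higher were Plau at 0.82 and Timp3 at 0.68, the latter with 0.37 and 0.17 on its other probes. Among the lower was Ctsb at -0.42. The p53 targets had a mean of -0.06 (adjusted p = 0.528), with Gadd45b called, and 2 higher and 2 lower when adjusted over the list alone. The higher were Gadd45b and Plk3, the latter at 0.55. The lower were Ddit4, at -0.67, and Trp53inp1, at -0.68 (other probe -0.50).

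Single members stood out in other lists. In the Notch list, with a mean of 0.10 and a median of -0.0048 (camera, adjusted p = 0.499), 2 genes were higher when adjusted over the list alone and 0 over all genes. The target gene Hes1 differed by 1.45 (adjusted p = 0.0582 over all genes), and the ligand gene Jag1, not above background on any control array, was at least 1.42-fold higher in FEAT clones on the background-corrected scale (adjusted p = 0.0995), with uncorrected intensities of 88.7 and 119. Notch was the 1 list that passed fry (adjusted p = 0.00986), which asks whether a list moves on balance one way and does not compare it with other genes. Chac1 fell in the unfolded protein response list and was the 1 gene lower when adjusted over the list alone. That list's mean was -0.045 and its camera direction upward (adjusted p = 0.909). In adhesion and junctions (mean 0.098, adjusted p = 0.246, but 0.15 and 0.0456 without control 3 and 0.16 and 0.0272 without FEAT 20) 0 genes were called over all genes, and the integrin gene Itgb7, at -1.33, was lower when adjusted over the list alone. The same was true of catalase, Cat, at -0.59 (its other probe was not above background on any array) in oxidative stress defence (mean -0.10, adjusted p = 0.325, but -0.23 and 0.00804 without FEAT 3) and of Ndrg1, at -0.80 (other probe -0.57), in hypoxia and glycolysis (mean 0.0040, median -0.0091, camera direction downward, adjusted p = 0.892).

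None of the 7 lists of other cell types' markers passed. Bone and cartilage markers had a mean of -0.15 (adjusted p = 0.0926, but -0.21 and 0.0122 without FEAT 15), with Bglap2 the 1 gene lower both over all genes tested and when adjusted over the list alone. In muscle markers (mean -0.012, adjusted p = 0.566) 0 were called over all genes, and the troponin genes Tnni1 and Tnnc1 were lower when adjusted over the list alone. Tnnc1 differed by -0.52, and Tnni1 was not above background on any FEAT array and was at least 1.18-fold lower there. In macrophage and leukocyte markers (mean -0.0063, adjusted p = 0.909) 0 were called over all genes, and the T-cell receptor component Cd3e was the 1 gene past the threshold when adjusted over the list alone. Its intensity of 74.5 in control and 94.0 in FEAT clones lay above background on 0 of 3 control and 1 of 3 FEAT arrays, so no fold is given. Adipocyte, endothelial, epithelial and neural markers had means of -0.08, 0.09, 0.09 and -0.03 (adjusted p = 0.393, 0.393, 0.459 and 0.845). Some of their members, such as Adipoq, Pecam1 and Dcx, were not above background on any array, while Plin2, Lpl, Eng and Krt14 were on every array. For members near background, a mean near 0 does not show that expression stayed the same.

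In 13 lists no member passed either over all genes tested or adjusted over the list alone. They were those 4 marker lists and the 9 that follow. G1/S and DNA replication genes had a mean of 0.097 (adjusted p = 0.0910, but 0.0420 without normexp, 0.0458 with an offset of 50, 0.0326 with the deposited value table, 0.0273 without control 3 and 0.0454 without FEAT 3), G2/M and mitosis genes of 0.066 (adjusted p = 0.363) and translation elongation and initiation genes of 0.087 (adjusted p = 0.161). Pro-apoptotic genes had a mean of 0.036 (adjusted p = 0.909) and anti-apoptotic genes of -0.061 (adjusted p = 0.501). The hedgehog pathway had a mean of 0.012 (adjusted p = 0.528) and receptor tyrosine kinases of 0.037 (adjusted p = 0.566). The interferon response had a mean of -0.080 (adjusted p = 0.363, but -0.19 and 0.0258 without control 3), and MHC class I and complement genes of -0.066 (adjusted p = 0.393). Mean and median differed in sign in the Notch, hypoxia, unfolded protein response and protease lists, the last with a median of -0.030.

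The clones of a group were also compared with each other. The median SD per probe was 0.155 on the log2 scale over the FEAT clones and 0.168 over the control clones, and 46.0% of probes had the higher SD among FEAT clones. With 3 clones per group this difference was not tested. Across tested probes, the mean Pearson correlation was 0.991 between FEAT clones, 0.990 between control clones and 0.989 between groups, where probes are not independent replicates. Control 1 and control 3 were the closest pair, with 49 probes at least 2-fold apart, against 258 and 319 for control 2 with each of them and 191 to 219 between FEAT clones. Every other pair of arrays, within or between groups, differed at 191 probes or more, so control 1 and control 3 were unusually alike. The calls rested partly on this pair: limma called 158 probes without control 2, but 0 without control 1 and 10 without control 3. If these clones are not fully independent, the spread among controls may be understated, which was not tested.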

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

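The background limit was chosen after the data were seen, and all alternatives here were planned. Detection at p under 0.01 on all 6 arrays was not run, since the tables used here give no detection p, and a slide block was not run, since no slide was given. No paired analysis was possible because the clone numbers only name clones and the groups share 1 of them. All 50 called probes kept their sign in every alternative. This lends the calls no support, since their groups did not overlap and leaving out a clone could hardly reverse a sign. Under the scaling, background, filter and variance settings 38 to 68 probes passed. Arrays read 39.4% to 43.0% of probes above background, which limits what can be said of dim genes such as Tmem181a, Atp9a and Mroh1. The count ran from 0 without control 1 to 158 without control 2, and 4 probes passed at an adjusted p under 0.01. Genes at least 2-fold apart numbered 32 without normexp and 32 with the deposited value table, 234 at 1.5-fold, where the looser limit sets the count, and 47 to 105 over the omissions of a clone. An omission leaves fewer clones to separate, which by itself makes no overlap more frequent. Where no cause is given below, the cause was not tested.

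The cholesterol, matrix, contractile and TGF-beta lists kept their camera calls in all 7 scaling, filter and probe settings and in all 6 omissions of a clone, with ranges over the omissions of -0.62 to -0.36, 0.22 to 0.40, 0.36 to 0.60 and 0.26 to 0.47. All these calls used the preset correlation of 0.01. With the estimated correlation 0 lists passed, and with fry only the Notch list did, so the 6 camera calls were all lost. For cholesterol genes the camera adjusted p went from 5.92e-12 to 0.462 with the estimated correlation, and fry gave 0.208. The list means do not depend on the test, so they lend the calls no support here. They were 0.30 for matrix, 0.46 for contractile, 0.34 for TGF-beta, 0.21 for Wnt, 0.17 for inflammatory and -0.50 for cholesterol genes. The Wnt mean was 0.18 with the deposited value table, past the threshold no longer, and 0.19 to 0.24 over the omissions. The inflammatory mean lost its call at 0.14 without normexp, 0.14 with an offset of 50, 0.15 with the value table, 0.084 without a filter and 0.14 with the mean of all probes, and ran from 0.084 to 0.25 over the omissions (adjusted p 0.00767 to 0.460).

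Lists that had not passed and whose means lay near 0 changed sign. Receptor tyrosine kinase ligands gave 0.0049 without normexp, 0.0043 with an offset of 50, 0.0058 with median scaling, 0.018 with the value table and 9.50e-04 without a filter, and -0.062 to 0.075 over the omissions. Hypoxia and glycolysis gave -0.0041 without normexp, -0.0030 with an offset of 50 and -3.36e-04 with cyclic loess, and -0.049 to 0.060 over the omissions. Over the omissions alone, hedgehog ran from -0.026 to 0.088, pro-apoptotic genes from -0.011 to 0.094, p53 targets from -0.16 to 0.054, proteases from -0.0053 to 0.084, interferon from -0.19 to 0.015, the unfolded protein response from -0.099 to 0.013, muscle markers from -0.066 to 0.033, macrophage markers from -0.077 to 0.066 and neural markers from -0.097 to 0.0092. Single genes that changed sign were Adipoq, at -0.29 to 0.0014, and the brightest and the last of the 5 Eef1aknmt probes, at -0.11 to 0.11 and -0.25 to 0.055. None of these had passed in the setting the report uses. Some lists passed camera only under an alternative: G1/S and DNA replication without normexp, with an offset of 50 and with the value table (adjusted p = 0.0420, 0.0458 and 0.0326), and without control 3 or FEAT 3 (0.0273 and 0.0454). Without control 3, MAPK feedback, interferon and adhesion genes also passed (0.0163, 0.0258 and 0.0456), without FEAT 20 MAPK feedback and adhesion genes (0.0272 for both), without FEAT 3 oxidative stress genes (0.00804) and without FEAT 15 bone and cartilage markers (0.0122).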

Other observations

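The genes in the next paragraph were chosen after their values were seen. Tests of scaling, of single clones, of control 1 and of array brightness, and the look at each list over the splits, were chosen only after the result was seen. The 3 added lists were written after the other results and before their genes were looked at.

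Several genes differed at least 2-fold with no overlap between the groups and did not pass the adjusted threshold. Ankrd1, a mechanically responsive nuclear cofactor, had log2 differences of 1.63 and 1.52 on its probes (limma, adjusted p = 0.0887 and 0.122), and the cytochrome P450 gene Cyp1b1 of 1.85 (adjusted p = 0.210). On the lower side were Slc27a1, a fatty acid transporter, at -1.32 (adjusted p = 0.125), Plin4, a lipid droplet protein, at -1.26 (adjusted p = 0.248), and Fam180a, at -1.37 and -1.36 on its probes. Among early response genes outside the lists fixed at the start, Jun differed by 0.68 (adjusted p = 0.0995), Csrnp1 by 0.74 and Bhlhe40 by 0.70, whereas Dusp1 differed by -0.42.

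The 10 splits of the 6 clones into 3 and 3 are too few for a share under 0.05. The real split called 50 probes, and the highest other split 4, so that 1 split gave as many. For genes at least 2-fold apart the values were 52 and 33, again with 1 split as large. For lists they were 6 and 11, and 4 of the 10 splits called at least 6 lists. The split that called 11 lists set control 1, control 2 and FEAT 20 against control 3, FEAT 3 and FEAT 15. The camera call of the cholesterol list occurred in 6 of the 10 splits, and its mean was largest in the real one, with 0.38 in size as the highest other. The contractile list was called in 4 splits, with 0.39 as the highest other size beside 0.46. Another split gave a larger mean than the real one for the TGF-beta list, 0.37 against 0.34 in size, and for the inflammatory list, 0.22 against 0.17, where 3 of the 10 splits were as large.

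The lower cholesterol synthesis genes may reflect lower activity of SREBP, the transcription factor family that drives them. Scaling between arrays is argued against, since the list's mean was -0.49 (SE over clones 0.20) under the scaling that left it smallest against its error. A high level in control 1 alone is argued against, since the mean was -0.36 (SE 0.11) without that clone. In 14 measured SREBP targets outside the list, such as Elovl6 at -0.86 and Acss2 at -0.56 (other probe -0.14), the mean was -0.28 and 11 were negative. Camera gave p = 7.31e-05 and p = 0.0720 with an estimated correlation, which leaves lower SREBP activity open, and the FEAT insert itself is untested as its source.

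The higher contractile genes, with Ccn2 and Ankrd1, may reflect an early response, or activity of SRF or of YAP and TEAD, which drive such genes in fibroblasts. Scaling between arrays is argued against, with a mean of 0.46 (SE 0.16) under the scaling that left it smallest against its error. A single FEAT clone as the whole cause is argued against, since the list's mean was 0.67 in FEAT 3 and 0.53 in FEAT 15 against -0.065 to 0.075 in the controls (SD 0.071), with FEAT 20 lower, at 0.18. The group difference was 0.36 (SE 0.18) without FEAT 3, 0.43 (SE 0.24) without FEAT 15 and 0.60 (SE 0.080) without FEAT 20, so the omissions alone do not settle it. In 27 measured early response genes the mean was 0.15 and 18 were positive, with camera p = 0.00506 and p = 0.0793 with an estimated correlation. In 18 measured YAP and TEAD targets the mean was also 0.15 and 12 were positive, with p = 0.0223 and p = 0.0845 with an estimated correlation. An early response and YAP and TEAD activity stay open. SRF activity was not tested, since the early response list is not a list of SRF targets. The FEAT insert itself is untested as the source of any of them.

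Control 2 stood apart from the other controls, at -33.1 on the second principal component (23.8% of the variance) against -1.66 and 13.1. On the first (30%) it lay at -0.16, between the other controls at -26.8 and -25.3 and the FEAT clones at 12.9 to 21.6. A candidate explanation is array brightness or background, and control 2 lay outside the range of the other 5 arrays in 0 of 5 measures. These were mean and median intensity, background, its SD and the share of probes above it. Any array often lies inside such a range, so the measures cannot exclude a difference between arrays, which stays open. Its highest single intensity, 42981, did lie below those of the other arrays, 45028 to 49526. A difference between clones that arose during selection or culture may remain, and it was not tested. Control 2 may also stand apart only because control 1 and control 3 were unusually alike. That pair had 49 probes at least 2-fold apart, and every other pair of arrays 191 or more. Why the pair was so close was not tested.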
